A study of Arabidopsis thaliana with 16 samples.

How the data were processed

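Gene expression was measured in 16 samples of whole Arabidopsis rosettes, 4 per group, each a pool of 12 rosettes harvested 36 days after sowing. Per the labels' protocols, RNA was labelled with Cy3 or Cy5 by a 2-colour kit and hybridised to Agilent Arabidopsis 4x44K arrays (V4). The design is a modified loop of 8 arrays on 2 slides, in which each sample was labelled once and each group 2 times with each dye. No array pairs control with the combined treatment or heat and drought with elevated CO2 alone.

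The deposited values are normalized log2 intensities, with 1 column per dye channel, and the unit was read from the values and tested against them. The processing notes of the submitters name limma, with the version not given. Background correction, normalization within and between arrays, the filter on probes and the averaging of spots are not stated in the labels, so the scale of a ratio on each array is not known. The 16 columns have nearly equal medians (7.03 to 7.06) but are not identical, and the closest pair of columns differs by a root mean square of 0.163. The table has 19394 entries. After 30 control spots were set aside, 19364 probes were tested. Gene names came from the platform annotation and a TAIR10.1 gene table, used for names only because the files name no genome build. Of the probes tested, 17005 had 1 gene, 0 had several and 2359 were unnamed, for 12880 genes, 3208 of them with more than 1 probe. A gene is represented by its probe with the highest mean. Arrays hold no counts, so no depth per sample applies.

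The tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The design fixed before the data were examined is a per-sample fit of all 16 samples with group means, a fixed dye term and array as a random block (consensus correlation 0.689), eBayes, two-sided tests, Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. It was applied to 6 comparisons with the groups as labelled. After the samples were seen not to group by label, the loop was also split in 2 parts. Within arrays, the Cy5 minus Cy3 log2 ratios were fitted with a dye intercept, which equals a fit with array as a fixed block, an alternative named before the data were examined, and the results are given as labelled and with the sign turned. Between arrays, the means of the 2 columns of each array were fitted by array type, which compares the 2 arrays of stressed samples with the 2 of unstressed samples, and the 2 of elevated-CO2 samples with the 2 of ambient samples. Both parts have 4 residual degrees of freedom. A further per-sample fit had the labels of the 2 channels exchanged on every array. The sign turn and this exchange treat every array alike and were both chosen after the values were seen.

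Gene lists (29 lists, 598 entries, 455 of them measured) were written before the data were examined, and entries whose symbol belongs to another locus were dropped (3). Lists with at least 5 measured members were tested with cameraPR on the moderated statistics, with a preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals, and with fry. Adjustment was over the lists of a comparison. The estimated correlation was not allowed to be negative. As cameraPR compares genes with genes, its p does not measure the spread between arrays. The size of the stress response was a Deming slope over genes, with an exact permutation of the CO2 labels within the stressed and within the unstressed samples in 4900 arrangements.

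The rule for named genes was fixed in advance. It takes 12 markers where measured, the 6 largest rises and falls for heat and drought, the 4 largest for heat and drought at elevated CO2 and for the 2 CO2 effects, up to 3 members of each list past the threshold, and the 5 smallest p of the interaction. The largest changes had to pass the threshold, separate the samples completely and lie above the table's median level. Because the per-sample fit called no gene, the rule was applied to the between-array fit for heat and drought, with the 4 samples of each array type in place of groups, and to the within-array fit elsewhere, with agreement of both direct arrays in place of separation. That step was chosen after seeing the data.

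All fits were tested on simulated data with 19364 probes and planted changes. The simulated noise was independent between probes and took its size from the residuals of the within-array and between-array fits. Outside the exchange given below, no conflict between labels and arrays was simulated, nor were intermediate Cy5 columns. The shares recovered are therefore not the power of the fits on the real data. The per-sample fit recovered 99% or more of changes of 1 log2 unit in the 4 single-factor comparisons, the within-array fit 95% or more, and the between-array fit 82% for stress and 80% for CO2. Calls that were not planted ran from 20 of 220 to 31 of 230 per sample. They ran from 5 of 202 to 17 of 216 within arrays, and were 6 of 182 and 5 of 183 between arrays. The share was above 0.05 in each of these per-sample comparisons and in some within arrays. With the channels exchanged in the simulation, the between-array fit still recovered 82% of the stress changes and the per-sample fit 0%. A planted slope of 0.6 was estimated as 0.603. Alternatives covered normalization, dim probes, dye term, array and slide blocks, the replicate number, the prior, the samples in the fit, the threshold, probes per gene, the set test, each sample or array left out and, added after the data were seen, an interaction on a common scale. Nothing but the control spots was left out of the comparisons reported.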

Results

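Whole rosettes of Arabidopsis thaliana (accession Columbia) were sampled 36 days after sowing under 4 growth regimes. Each group had 4 samples, and each sample was a pool of 12 rosettes. Control plants grew at 380 ppm CO2 with 21 °C by day, 18 °C by night and a soil water target of 70%. A heat wave with drought began on day 32 and rose in steps to 38 °C by day and 30 °C by night, with a soil water target of 45%. It was given at 380 ppm or at 730 ppm CO2. The last group grew at 730 ppm CO2 without stress. The title of the series asks whether elevated CO2 eases the effect of a heat wave combined with drought. The samples were hybridised in pairs to 8 arrays, with Cy3 in one sample and Cy5 in the other, and 16 columns of normalized log2 intensity were deposited. Column medians ran from 7.03 to 7.06 over 19364 probes of which 17005 name 12880 genes, and the number of arrays limits the precision.

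Most heat and dehydration marker transcripts did not follow the sample labels on the 4 arrays that paired a sample labelled stressed with a sample labelled unstressed. HSP101, a chaperone that dissolves protein aggregates, measured 10.97 in the sample labelled control replicate 1 and 8.64 in the sample labelled heat_drought replicate 3 on the same array. The heat shock factor gene HSFA2 differed from this pattern. It opposed the labels on array 1.4 (10.36 labelled control against 8.08 labelled stressed) and was higher in the sample labelled stressed on the other 3 mixed arrays, for example 6.77 against 6.50 on array 2.1. On the other 4 arrays both samples carried the same stress label, and HSP101 lay between 8.94 and 10.76 on the 2 stressed arrays and between 6.27 and 6.48 on the 2 unstressed arrays. The stressed-minus-unstressed ratio of each mixed array, as labelled, ran against the difference between the stressed and the unstressed arrays, with Pearson's r over probes of -0.78, -0.85, -0.88 and -0.86. Probes are not independent replicates, so no p is attached to these correlations. Samples of the same labelled group were less alike (median r 0.939) than samples of different groups (median r 0.961). The pairs of different groups include the 2 columns of each array (median r 0.982), so this also reflects shared arrays. Because the ratios ran against the labels, it is not settled by the data whether a group label belongs to the Cy3 or the Cy5 column. Samples are named here by their labels.

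**Figure D1:**
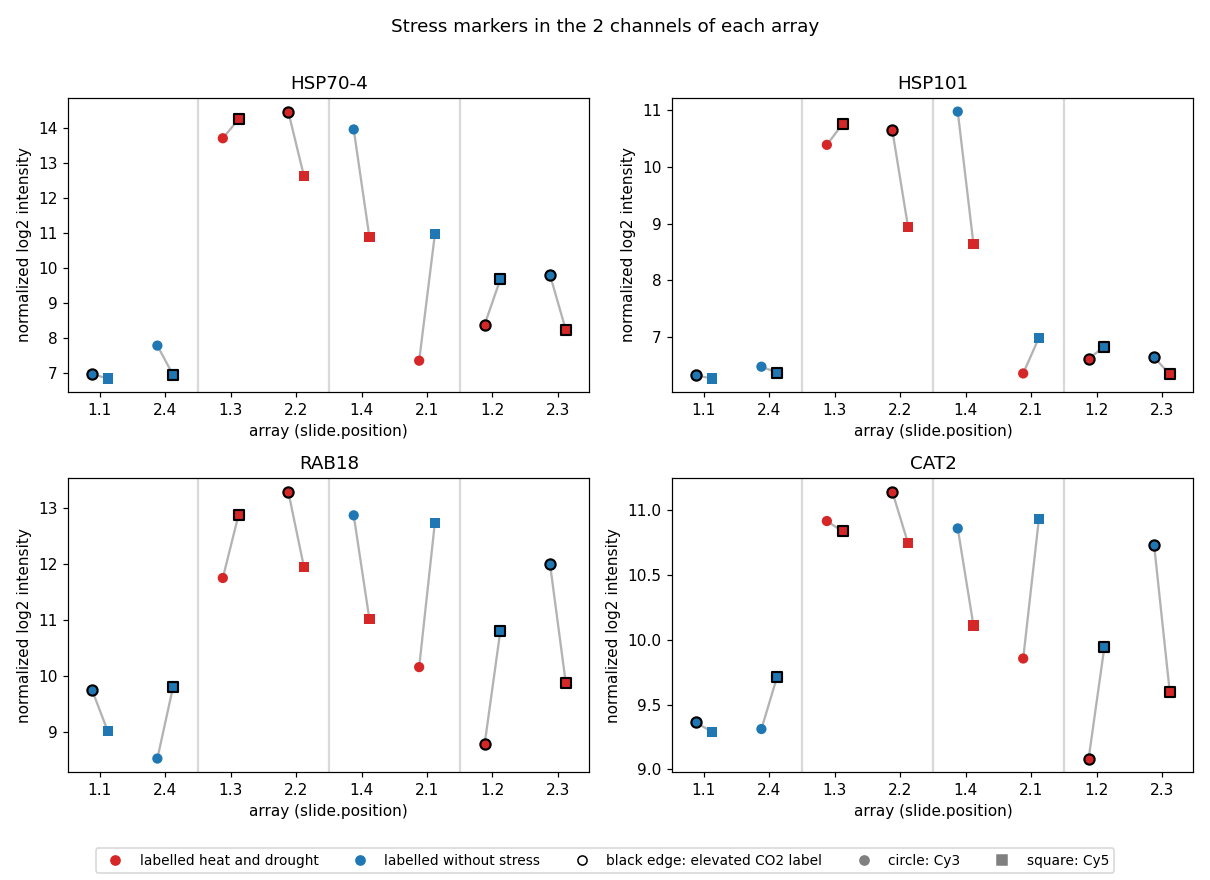
Normalized log2 intensity (vertical axis) of HSP70-4, HSP101, RAB18 and CAT2 in both columns of each of the 8 arrays (horizontal axis, slide and position), with a line joining the 2 samples of an array, red for samples labelled stressed, blue for unstressed, a black edge for elevated CO2, circles for Cy3 and squares for Cy5. On the 4 mixed arrays, to the right, the sample labelled unstressed lies higher for all 4 genes, for example 10.97 against 8.64 for HSP101 on array 1.4.

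In the per-sample fit as labelled, with limma, none of the 6 comparisons had a probe past an adjusted p of 0.05. At an unadjusted p under 0.05 there were 5526 probes for heat and drought at ambient CO2, 1155 for heat and drought at elevated CO2, 621 for elevated CO2 without stress, 1178 for elevated CO2 under stress, 1724 for the combined treatment against control and 1896 for the interaction. These zero counts depend on the fit. With slide added as a fixed block, limma called 9513 probes for heat and drought at ambient CO2, 22 for elevated CO2 under stress and 211 for the interaction. A fit of only the groups compared called 4171 for elevated CO2 under stress, and leaving out 1 sample at a time gave 0 to 5655 for heat and drought at ambient CO2. The fit without slide recovered 99% or more of simulated changes of 1 log2 unit in the first 4 of these comparisons. That simulation took its noise from the within-array and between-array residuals and held no conflict between labels and arrays. Its 99% is not the power of the fit on these data. The same fit recovered 0% of simulated heat and drought changes once the 2 channels of every simulated array were exchanged. The comparisons were therefore also made in parts that treat the labels differently, a step added after the data were seen. Differences between whole arrays do not depend on which column is which. Ratios within arrays do, and are given with the sign turned, that is, with the 2 labels of every array exchanged. As labelled, each of those values has the same size and the opposite sign.

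The first question was what the heat wave with drought did to the rosette transcriptome. Cytosolic small heat shock proteins, which bind unfolding proteins, led the rises, with AT1G53540 (HSP17.6C, log2 change 7.39) and AT2G29500 (HSP17.6B, 6.90). The chaperones HSP70-4 (AT3G12580, 6.62) and HSP90.1 (AT5G52640, 5.73), the peptidyl-prolyl isomerase gene AT5G48570 (ROF2, 5.80) and AT1G07400 (HSP17.8, 5.61) followed. Genes tied to pathogens or salicylic acid and an antenna protein gene were among the largest falls. These were PCC1 (AT3G22231, -5.65), which is under pathogen and clock control, AT3G22240 (-4.89), the salicylic acid regulator ACD6 (-3.78), the glutathione transferase GSTF6 (-3.76), the antenna protein gene LHCB2.3 (-3.65) and the pathogen-induced gene LURP1 (-3.62). These values compare the 2 stressed with the 2 unstressed arrays, in which 7727 probes (5201 genes) passed limma's threshold, 3832 of them higher and 3895 lower under stress. The count was 3151, 3605 or 4480 without array 1.3, 2.2 or 1.1. In limma the adjusted p of these genes ran from 0.0018 for ACD6 to 0.019 for LURP1. The naming rule admitted only genes past the threshold whose 4 samples on the stressed arrays lay beyond the 4 on the unstressed arrays. Neither property is therefore separate support for them, and the 4 samples are 2 arrays of 2 channels. Where these genes had several probes, the probes shared the direction but not the size, from 2.83 to 5.73 for HSP90.1 and from -3.65 to -0.66 for LHCB2.3.

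Among the genes fixed in advance, the dehydrin gene RAB18 rose by 3.19 log2 units (SE 0.35, limma adjusted p = 0.0021), although its 4 probes spread from 0.08 to 3.19. HSP101 rose by 3.82 (adjusted p = 0.012, limma), a size that is poorly measured because its 6.27 to 6.48 on the unstressed arrays lay under the lower quartiles of those columns, and background values were not available. The heat shock factor gene HSFA2 rose by 2.16 (limma adjusted p = 0.044). The photorespiratory catalase gene CAT2 (1.49, limma adjusted p = 0.0026), the proline synthesis gene P5CS1 (1.55, limma adjusted p = 0.0049) and the abscisic acid synthesis gene NCED3 (0.35, limma adjusted p = 0.048) also rose. The calls of 3 markers did not hold when arrays were left out. That of HSP101 was lost without array 1.1, 1.3 or 2.4, that of HSFA2 without any array but 1.4 or 2.1, and that of NCED3, a dim gene with control samples between 5.84 and 6.30, without any single array. APX1 (-0.06), RBCS1A (-0.15) and GPT2 (-0.10) did not pass the threshold, with limma adjusted p of 0.66, 0.30 and 0.74. The 14 probes of RBCS1A ran from -0.56 to 0.36, and its reported probe read at least 14.50 in every sample, near the top of the columns, so its value does not show a stable transcript. No probe named for APX2 or RD29B was in the table, in which 2359 probes have no gene name.

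Chaperones rose as groups. Of 18 measured small heat shock proteins 16 rose and 1 fell (median log2 3.79), and of 24 large chaperones and co-chaperones 18 rose and 0 fell (median 1.64). With cameraPR these lists had adjusted p of 1.5e-08 and 1.4e-09, and 0.19 for both with an estimated correlation. Heat shock factors and heat regulators rose in 6 of 14 members, led by MBF1C (4.85) and HSFB1 (1.86), with cameraPR adjusted p = 0.025, and 0.42 with an estimated correlation. Folding genes of the endoplasmic reticulum rose in 10 of 16 members, including ERDJ3A (1.21) and CNX1 (1.12), while CRT3 fell (-1.05). Their cameraPR adjusted p was 0.0061, and 0.25 with an estimated correlation. Aquaporins, the water channels, rose in 9 of 11 members, led by PIP2;1 (2.23), PIP2;7 (1.43) and PIP2;2 (1.14), with cameraPR adjusted p = 6.0e-05, and 0.067 with an estimated correlation.

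Light reaction, cell division and cell wall genes fell. Of 47 light reaction genes 40 fell and 1 rose (median -1.06), with LHCB1.1 (-3.09) and LHCB1.4 (-2.66, its 3 probes from -6.52 to -0.59) beside LHCB2.3. The cameraPR adjusted p was 2.1e-14, and 0.19 with an estimated correlation. Cell division and DNA replication genes fell in 9 of 11 members, among them TSO2 (-1.98), KNOLLE (-1.37) and MCM7 (-1.24), and cell wall expansion genes fell in 11 of 19, among them XTH9 (-2.67) and XTH4 (-2.32, with another probe at -0.50), while XTH7 rose (1.48). Both lists kept their call with an estimated correlation, at cameraPR adjusted p of 5.0e-04 and 0.0014. Salicylic acid defence genes fell in 10 of 13 members, including WRKY70 (-2.59), PR5 (-2.34) and WRKY54 (-1.71), with cameraPR adjusted p = 0.0054, and 0.42 with an estimated correlation. Adjusted over the list alone, the counts were 16 up and 1 down for small heat shock proteins, 20 up for large chaperones, 6 up for heat shock factors, 10 up and 1 down for folding genes, 9 up for aquaporins, 2 up and 40 down for light reactions, 9 down for cell division, 3 up and 12 down for cell wall and 10 down for salicylic acid defence.

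Water-stress genes moved in both directions. Among 16 dehydration-responsive proteins 5 rose and 5 fell, with RAB18 up and the cold-regulated genes COR15B (-2.43) and COR15A (-1.93) down. Abscisic acid genes rose in 13 and fell in 7 of 26 members, and the risers included the phosphatase genes HAI1 (2.27) and PP2CA (2.02) and the transcription factor gene ABF3 (2.00). The galactinol synthase genes GOLS1 (4.90) and GOLS2 (3.03), which start raffinose synthesis, rose. In cameraPR these 3 lists had adjusted p of 0.80, 0.12 and 0.19, so none was called as a list, which does not show that they did not move.

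**Figure D2:**
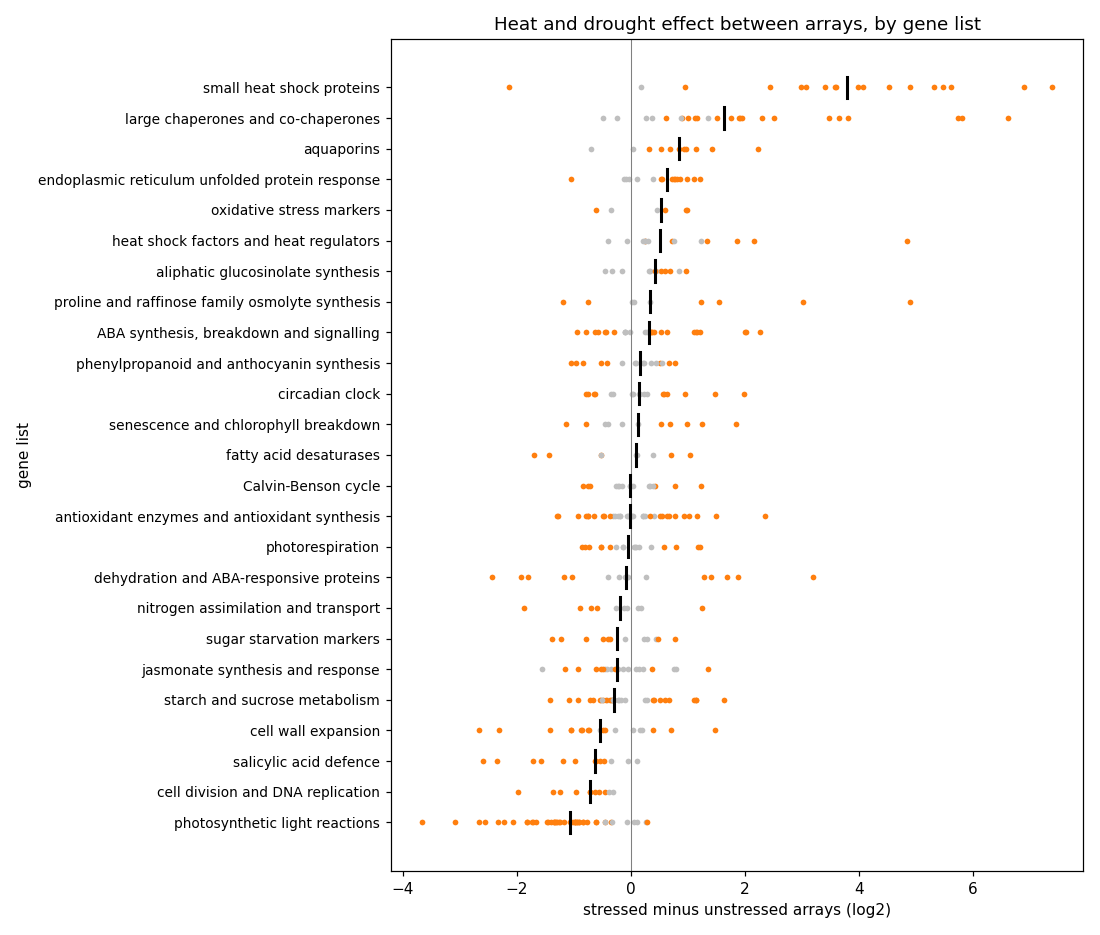
Log2 difference between stressed and unstressed arrays (horizontal axis) for each member of each tested gene list (vertical axis), with orange points for genes past limma's threshold, grey points for the others and a black bar at the list median. Small heat shock proteins (median 3.79) lie at the top and photosynthetic light reactions (median -1.06) at the bottom.

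The differences above average over CO2, since each stressed or unstressed array held 1 ambient and 1 elevated-CO2 sample. The response to heat and drought at elevated CO2 alone was taken within arrays. There HSP70-4, RAB18 and HSP101 changed less than between arrays at ambient CO2 too. A gap to the values above is therefore not by itself a CO2 effect. With the sign turned, AT2G29500 (3.35), AT1G53540 (3.09), the lipid transfer protein gene LTP4 (3.03) and AT2G07671 (2.94) led the rises, and AT3G22240 (-2.39), AT1G27020 (-2.22), AT3G05730 (-2.07) and PCC1 (-2.04) led the falls. RAB18 (2.05), CAT2 (1.00) and P5CS1 (0.78) rose, while HSP101 (0.30) did not pass the threshold (limma adjusted p = 0.31). Salicylic acid defence genes fell in 10 of 13 members (median -0.31), with cameraPR adjusted p = 4.5e-05, and 3.7e-05 with an estimated correlation. Small heat shock proteins rose in 13 of 18 members and light reaction genes fell in 39 of 47, at cameraPR adjusted p of 2.5e-09 and 8.3e-12, with 0.17 and 0.41 from an estimated correlation. Large chaperones (12 rose and 3 fell of 24), folding genes of the endoplasmic reticulum (9 of 16 rose), aquaporins (7 of 11 rose) and cell division genes (9 of 11 fell) also had calls, at cameraPR adjusted p of 0.0014, 0.0096, 6.1e-04 and 0.0021, with 0.41, 0.41, 0.17 and 0.41 from an estimated correlation. Heat shock factors (3 of 14 rose) and cell wall genes (3 rose and 6 fell of 19) had none, at cameraPR adjusted p of 0.33 and 0.26. Adjusted over the list alone, 10 defence genes were down, 13 small heat shock protein genes were up and 1 down, 40 light reaction genes were down and 2 up, 12 large chaperones were up and 4 down, 9 folding genes were up and 1 down, 7 aquaporins were up and 9 cell division genes were down. Within arrays 6850 probes passed limma's threshold, 3415 higher and 3435 lower with the sign turned, and 4337 did without array 1.2. At ambient CO2 the corresponding count was 10477 probes, 5287 higher and 5190 lower with the sign turned. HSP70-4 rose by 3.25 there, RAB18 by 2.24 and HSP101 by 1.44. Both sets of ratios ran against the between-array difference as labelled, with r over probes of -0.93 at ambient and -0.91 at elevated CO2.

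**Figure D3:**
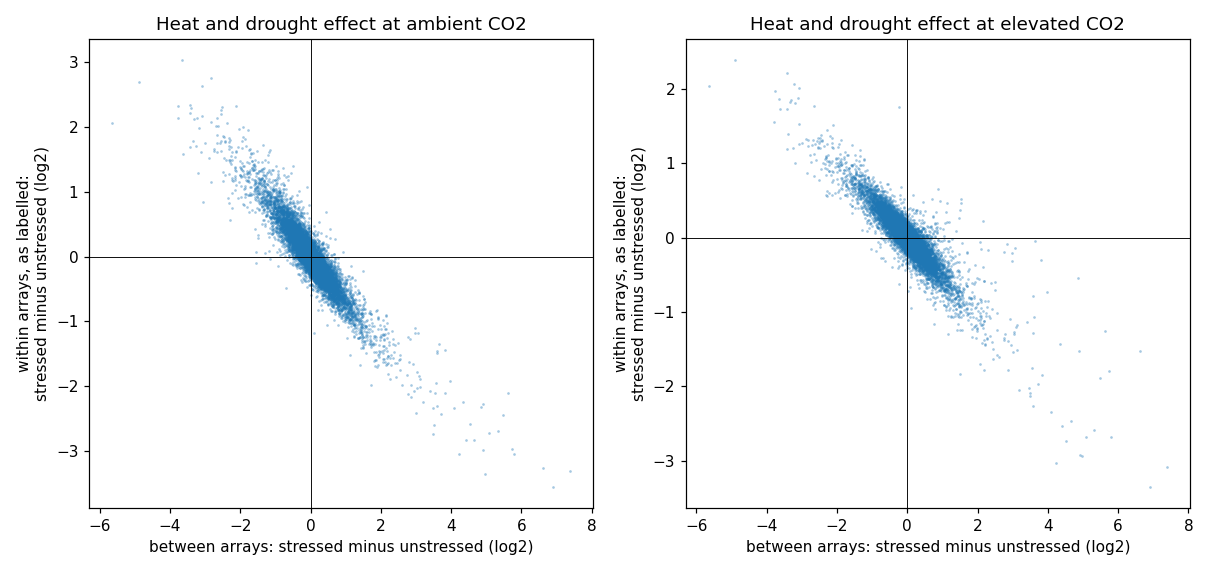
Each point is a probe, with the log2 difference between stressed and unstressed arrays on the horizontal axis and the within-array log2 stress effect as labelled on the vertical axis, at ambient CO2 (left) and elevated CO2 (right). The clouds slope downward, with r of -0.93 and -0.91.

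The next question was what elevated CO2 did without stress. With the sign turned, the pathogenesis-related gene PR4 (0.93), AT5G64550 (0.75), AT1G64360 (0.66) and AT3G22550 (0.56) rose at elevated CO2. RAB18 (-1.03), the xylosidase gene XYL4 (-0.90), the nitrate reductase gene NIA1 (-0.78) and the sugar transporter-like gene AT1G19450 (-0.69) fell, as did COR15A (-0.53). Dehydration-responsive proteins shifted down (median -0.26), with cameraPR adjusted p = 6.9e-07, and 6.4e-08 with an estimated correlation. Sugar starvation markers also shifted down (median -0.29, cameraPR adjusted p = 4.6e-06, and 0.041 with an estimated correlation). Adjusted over the list alone, 7 dehydration genes were down and 1 up, and 8 starvation markers were down. Only 33 probes (18 genes) passed limma's threshold within arrays, 18 higher and 15 lower with the sign turned, and 0 did without array 1.1, 1.2 or 2.1.

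The difference between arrays of elevated-CO2 and ambient samples, which does not depend on the order of the columns, gave 0 probes past limma's threshold and 1764 at an unadjusted p under 0.05. Its lists shifted the same way. Dehydration-responsive proteins (median -0.61) had cameraPR adjusted p = 7.2e-15, and 4.6e-17 with an estimated correlation, and sugar starvation markers (median -0.39) had cameraPR adjusted p = 4.8e-10, and 4.2e-11 with an estimated correlation. For both lists the estimated correlation gave the smaller adjusted p, so it was not the stricter test. Proline and raffinose synthesis lay lower (median -0.69) and aliphatic glucosinolate synthesis, which makes defence compounds from methionine, lay higher (median 0.39). Their cameraPR adjusted p with an estimated correlation were 0.0047 and 0.0040. Large chaperones lay lower (median -0.44, cameraPR adjusted p = 7.1e-05), and 0.34 was the adjusted p with an estimated correlation. The 2 ambient arrays differed in heat genes. On a scale of 0 for unstressed and 1 for stressed arrays, the median of 40 heat genes was 0.75 on ambient array 1.4 and 0.27 on ambient array 2.1. It was 0.22 and 0.32 on elevated-CO2 arrays 1.2 and 2.3, so only array 1.4 lay above both. Adjusted over the list alone, 7 dehydration genes, 5 starvation markers, 2 proline and raffinose genes and 0 chaperones were down, and 1 glucosinolate gene was up. These arrays each pair a stressed with an unstressed sample, so the values average over stress.

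Under heat and drought, the fit within arrays put several chaperone transcripts lower at elevated CO2 when the sign was turned, but the 2 arrays that compare these groups directly differed. For HSP101 the 2 columns read 10.65 and 8.94 on array 2.2 and 10.76 and 10.39 on array 1.3. Over 40 heat genes the median difference with the sign turned was -0.64 on array 2.2 and 0.01 on array 1.3. HSP70-4 (-1.28), AT5G35660 (-1.22), RAB18 (-1.22) and HSP101 (-1.08) led the falls under the naming rule, and the heat regulator gene MBF1C, named as a list member, fell by 1.31. The sulphur deficiency gene ATSDI1 (1.41), the beta-amylase gene BAM5 (1.27), the mitochondrial carrier gene DIC2 (1.17) and the transcription factor gene WRKY40 (1.11) led the rises. Large chaperones shifted down (5 of 24 past the threshold, median -0.49) with cameraPR adjusted p = 8.6e-15, and 0.013 with an estimated correlation. Dehydration-responsive proteins shifted down (median -0.28), and cell wall expansion (median 0.25) and jasmonate genes (median 0.21) shifted up, each also with an estimated correlation (cameraPR adjusted p of 2.7e-08, 2.7e-08 and 1.3e-09). That second test is not stricter for a list whose estimated correlation lay under the preset. Light reaction genes shifted up (median 0.28, cameraPR adjusted p = 3.7e-15), and the adjusted p was 0.21 with an estimated correlation. Adjusted over the list alone, 14 chaperones and 8 dehydration genes were down, 8 cell wall genes were up and 1 down, and 10 jasmonate genes and 21 light reaction genes were up. Within arrays 369 probes (250 genes) passed limma's threshold, 218 higher and 151 lower with the sign turned. The count was 5 without array 2.2 and 81 to 585 without each of the others. Without array 2.2, in leave-outs added after the data were seen, HSP70-4 (-1.05) and HSP101 (-0.92) lost their call in limma (adjusted p of 0.19 and 0.24), and the large chaperone median was -0.39.

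The interaction asks whether the response to heat and drought differed between CO2 levels, which is the question of the series. With the sign turned, stress raised HSP70-4 by 3.25 at ambient and 1.52 at elevated CO2, an interaction of -1.73 (SE 0.25, limma adjusted p = 0.017), and HSP101 had an interaction of -1.14 (SE 0.25, limma adjusted p = 0.040). In leave-outs added after the data were seen, HSP70-4 ran from -1.98 to -1.43 and lost its call without array 1.1, 1.2 or 2.3. The HSP101 value draws on unequal arrays, with columns at 10.97 (the outlying sample labelled control replicate 1) and 8.64 on array 1.4, but 6.99 and 6.36 on array 2.1. In the added leave-outs it ran from -1.34 to -0.90, the latter without array 1.4, and it passed limma's threshold only without array 2.4 (adjusted p = 0.036). Its columns on the mixed arrays other than 1.4 read 6.35 to 6.99, near its unstressed level, so neither the difference nor its SE is well measured. The 5 genes with the smallest p were AT5G35660 (-1.33), the xyloglucan endotransglucosylase/hydrolase gene XTH4 (1.13), the glycosyltransferase gene UGT85A5 (-0.92), the phosphatase gene PAP17 (-0.85) and NIA1 (1.19). Each still passed limma's threshold whichever array was left out. AT5G35660, XTH4 and UGT85A5 have 2 probes each, whose stress changes between arrays were unequal in size. Their interaction is given for the brighter probe only. The large chaperone list had a negative interaction in 12 of 24 members past the threshold and a positive one in 0 (median -0.62), with cameraPR adjusted p = 1.1e-14, and 0.021 with an estimated correlation. Cell wall expansion (median 0.39) and jasmonate genes (median 0.21) had positive interactions, with cameraPR adjusted p of 4.9e-09 and 7.1e-04 from an estimated correlation. Light reaction genes had 9 positive interactions of 47 (median 0.36, cameraPR adjusted p = 1.1e-14), and the adjusted p was 0.23 with an estimated correlation. Adjusted over the list alone, 18 chaperones were negative, 11 cell wall genes positive and 1 negative, 9 jasmonate genes positive and 1 negative, and 33 light reaction genes positive and 1 negative. In limma 876 probes (576 genes) passed within arrays, 431 positive and 445 negative with the sign turned, and 14, 9, 19, 117 or 419 were left without array 1.1, 1.2, 2.1, 2.3 or 1.3. A smaller response of all genes at elevated CO2 would by itself make risers negative and fallers positive. In a test added after the data were seen, the ambient response was first multiplied by the all-gene slope of 0.702, taken as known. Then 116 probes passed in limma, HSP70-4 (-0.76, adjusted p = 0.17) and HSP101 (-0.71, adjusted p = 0.18) did not, and the 5 genes did. With an estimated correlation, cell wall expansion (median 0.18) and jasmonate genes (median 0.15) kept their call (cameraPR adjusted p of 2.8e-06 and 1.6e-04). With the preset correlation the cameraPR adjusted p were 8.7e-06 and 1.15e-04, so the estimate was not the stricter test for cell wall expansion. Large chaperones (median -0.34) and light reaction genes (median 0.09) had none (cameraPR adjusted p of 0.21 and 0.73, and 3.2e-07 and 0.0038 with the preset correlation). As labelled, every sign in this paragraph is the opposite, so the sign of each interaction rests on the unsettled order of the columns. Which CO2 level had the larger change stays the same only if the labels of every array are exchanged together. HSP70-4 then changed in size by 3.25 at ambient and 1.52 at elevated CO2 either way. The fit also draws on the arrays whose samples share a stress label. An exchange on the mixed arrays alone could therefore alter these sizes, and it was not fitted.

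The size of the stress response was compared by a slope of the response at elevated CO2 on that at ambient CO2 over all genes. Within arrays this slope does not change when every ratio is turned, and it was 0.702 (r over genes 0.896), and it stayed between 0.653 and 0.756 when each array was left out in turn. With no effect simulated, the shared loop alone gave r = 0.362. Single pairs of arrays ranged from 0.369 to 0.880, and the ratio scale of each array was not known, so the slope carries no test. In the per-sample values as labelled the slope was 2.95, with a two-sided exact permutation p of 0.609 over 4900 arrangements, and it ran from -6.27 to 4.83 when each sample was left out in turn, so it has no settled sign. In the 11 lists with a call in that fit, no difference in the mean size of the response between CO2 levels passed the threshold (Benjamini-Hochberg adjusted p = 0.989 for each, exact permutation), with 0.64 log2 units more at elevated CO2 for large chaperones. These values share the limit of the per-sample fit if the channels are exchanged.

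The combined treatment was also set against control. Its ratios as labelled ran against the between-array stress effect, with r over probes of -0.88, and by the rule fixed in advance it adds no named genes. Within arrays 7888 probes (5318 genes) passed limma's threshold, 3936 higher and 3952 lower with the sign turned, although no array held both groups.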

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

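Of the tests below, those of the label conflict, of the intermediate Cy5 columns and of the heat shock genes at elevated CO2 were chosen only after the result was seen. The gene lists behind them were fixed before the data were examined.

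Of 40 combinations of marker gene and group, 3 held a sample far from the other 3, where chance gives about 1 in 20. HSP101 measured 10.97 and HSFA2 10.36 in the sample labelled control replicate 1, both far above the other control samples. NCED3 measured 6.18 in the sample labelled high_CO2 replicate 2, above the other samples of that group. Both samples lie on mixed arrays.

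The ratios of the 4 mixed arrays ran against the difference between stressed and unstressed arrays. A dye bias would give opposite signs in the 2 dye orientations, and the orientation with the stressed label in Cy5 had r of -0.85 nearest to 0, so dye bias is argued against as the cause. An exchange of columns on only some arrays would turn spike-in ratios there. The spike-in with the widest dye difference stayed higher in the Cy5 column on all 8 arrays (lowest log2 ratio 2.74), which argues against it, as do 5 others of the 10. The other 4, with mean ratios from -0.46 to 0.79, changed sign on some arrays and are too near 0 to tell. A candidate explanation that stays open is that the sample labels of the 2 channels are exchanged on every array, since all 4 mixed arrays opposed the labels (r nearest to 0, -0.78). The biological alternative, rosettes that answered heat with fewer chaperone transcripts, would have to hold on mixed arrays alone. The other arrays argue against it, since small heat shock proteins and large chaperones rose there as groups. HSP101 read 8.94 to 10.76 on the stressed and 6.27 to 6.48 on the unstressed arrays. HSP70-4 read 12.6 to 14.5 and 6.8 to 7.8. For the pools on the mixed arrays it was not tested.

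The Cy5 columns of the mixed arrays lay between the stressed and the unstressed level. On a scale where unstressed arrays average 0 and stressed arrays 1, these 4 columns scored 0.21 to 0.56, and the Cy3 columns scored 0.99, -0.02, 0.85 and 0.10. Carry-over of the Cy3 sample into the Cy5 column could add intensity and so favour rising over falling genes, and the smallest difference between them over the 4 columns was 0.0544. In the other 12 columns it ran from -0.101 to 0.0561, so 3 of the 4 columns lay above that spread and 1 within it, which leaves carry-over open. That spread was made the bound only after these values were seen. Pools that differed in stress cannot be told apart from it, since the scores span 0.355 and each pool was measured once.

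The interaction test within arrays passed its threshold for 7 named genes. With the sign turned, the interactions were -1.14 for HSP101, -1.73 for HSP70-4, -1.33 for AT5G35660, 1.13 for XTH4, -0.92 for UGT85A5, -0.85 for PAP17 and 1.19 for NIA1. As labelled, each has the opposite sign. The leave-outs and the scaled test given here were added after the data were seen. HSP101 passed limma's threshold only without array 2.4, HSP70-4 lost its call without array 1.1, 1.2 or 2.3, and the other 5 kept theirs whichever array was left out. With the ambient response scaled by the all-gene slope of 0.702, HSP101 (-0.71) and HSP70-4 (-0.76) lost their call and the other 5 kept theirs. The total of 876 probes fell to 9 without array 1.2 and to 116 with that scaling.

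Heat shock transcripts were low on the mixed arrays at elevated CO2 relative to other genes that rose under stress. Dilution with unstressed RNA, or carry-over, would leave heat genes at or above other risers, but 40 heat genes scored below 2499 other risers on both such arrays (-0.108, SE 0.037, on array 1.2 and -0.33, SE 0.066, on array 2.3). The ambient mixed arrays gave 0.19 (SE 0.023) on array 1.4 and -0.04 (SE 0.041) on array 2.1. Both elevated-CO2 values were below those of the ambient arrays. They are the pattern itself and no separate test of it, and the SE is over genes that are not independent. The ambient arrays also differ from each other by more than the value of array 1.2. Dilution is therefore left open. Weaker ratios on those arrays in general could contribute, since spike-in ratios there were 0.832 of those on the ambient mixed arrays. By array they were 1.55 on array 1.2 and 2.51 on array 2.3, against 1.94 on array 1.4 and 2.94 on array 2.1. Only array 1.2 was weaker than both ambient arrays, and its heat genes themselves had the lowest score (0.224). That score was 0.324 on array 2.3, against 0.266 on ambient array 2.1 and 0.752 on ambient array 1.4. Array 2.3 was lowest only relative to other risers. Weaker ratios are left open, with 2 arrays of each kind. A weaker heat shock response at elevated CO2 stays open as well. On the 2 arrays of stressed samples, the heat genes differed between CO2 levels by a median of 0.64 on array 2.2 and -0.01 on array 1.3 as labelled, so the sign rests on the order of the columns.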

How the results depend on the processing

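The channel exchange and all alternatives to the within-array and between-array results were chosen only after the result was seen. The other alternatives were fixed before the data were examined.

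Per sample, limma called 0 probes in each comparison (5526, 1155, 621, 1178, 1724 and 1896 at an unadjusted p under 0.05, in the order used throughout: stress at ambient CO2, stress at elevated CO2, CO2 without stress, CO2 under stress, combined treatment, interaction). With array as a fixed block, a fit that uses ratios within arrays alone, the counts were 10477, 6850, 33, 369, 7888 and 876. With the channels exchanged on every array they were 12399, 9522, 630, 728, 10640 and 1261. A fixed slide block gave 9513 for stress at ambient CO2, 22 for CO2 under stress and 211 for the interaction. A fit of only the groups compared gave 2 for CO2 without stress and 4171 for CO2 under stress. The interaction had 6 calls without the dimmest 25% of probes, 5 with 1 probe per gene and 7 without the dye term. Median centring, quantile normalization, no array block, a trend in the prior and each slide alone gave no call. For these differences the cause was not tested.

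Leaving out each sample in turn gave 0 to 5655 calls for stress at ambient CO2, with 5655 without heat_drought_high_CO2 replicate 4 and 1801 without heat_drought replicate 4. It gave 0 to 30 for CO2 under stress and 0 to 40 for the interaction, both highest without heat_drought replicate 3. Without heat_drought_high_CO2 replicate 4 these had 2 and 2, and the interaction had 6, 1, 5 and 1 without control replicate 4, heat_drought replicate 1, heat_drought replicate 4 and high_CO2 replicate 3. The other comparisons stayed at 0. The size slope moved from -6.27 (without control replicate 2) to 4.83 (without heat_drought_high_CO2 replicate 1), with exact permutation p from 0.286 to 0.987. List calls moved from 39 to a range of 31 to 48, and were 63 with array as a fixed block, 63 within slide 1, 1 with an estimated correlation and 5 with fry.

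With the replicate number as a block, 0 probes were called in all 6 comparisons and 36 lists. Samples sharing a number correlated from -0.93 to 0.85, 2 of 6 pairs per number were above 0.1, and 0 of 16 samples fitted best with their own number, so the number does not pair them.

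Within arrays, an absolute log2 change of at least 1 left 910, 364, 2, 14, 625 and 34 probes. The 33 calls for CO2 without stress became 52 with centring, 64 with quantile normalization, 16 with 1 probe per gene, 0 without the dye term (2857 at an unadjusted p under 0.05 with it), 55 with a slide term and 121 with a trend. CO2 under stress had 43 without the dye term and 596 with a trend, and the interaction 28 and 1347. Leaving out each array gave 7665 to 10566, 4337 to 7075, 0 to 187, 5 to 585, 5703 to 7450 and 9 to 822 probes. The 4337 came without array 1.2, the 187 and 585 without array 1.4 and the 5 without array 2.2. CO2 without stress had 0 calls without array 1.1, 1.2 or 2.1, 4 without 1.3, 1 without 2.2, 8 without 2.3 and 2 without 2.4. CO2 under stress had 136 without 1.1, 81 without 1.2, 116 without 1.3, 146 without 2.1 and 109 without 2.4. The interaction had 14 without array 1.1, 9 without 1.2, 419 without 1.3, 19 without 2.1 and 117 without 2.3. With the ambient response scaled by the all-gene slope it had 116. Lists fell from 63 calls to 17 with an estimated correlation.

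Between arrays, 1699 probes changed by at least 1 log2 unit under stress, and leaving out each array gave 3151 to 7819 (4480 without array 1.1, 3151 without 1.3, 3605 without 2.2). For CO2 there were 3 calls with 1 probe per gene, 17 with a trend and 0 to 65 with an array left out (65 without 1.4, 59 without 2.1). Lists fell from 22 calls to 9 with an estimated correlation. Over 139 alternatives for the 10 marker genes, 120 kept their side of the threshold, 19 lost a call and 0 crossed it with the opposite sign. Short of the threshold, the sign changed with an array left out for GPT2 (-0.36 to 0.15) and APX1 (-0.12 to 0.01). HSP101 lost its call without array 1.1, 1.3 or 2.4, HSFA2 without any array but 1.4 or 2.1, and NCED3 without any single array.

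Per sample, 272 of 299 marker alternatives kept their side of the threshold, 18 passed it and 9 crossed it with the opposite sign, all 9 with the channels exchanged. The values then were 1.98 for HSP101, 4.02 for HSP70-4, 1.23 for HSFA2, 2.43 for RAB18, 0.18 for NCED3, -0.32 for RBCS1A, 1.01 for CAT2, -0.98 for GPT2 and 0.95 for P5CS1. The sign itself was less stable than these counts, also with the labels kept. With each sample left out in turn, it changed for HSP70-4 (-2.62 to 1.58) and RAB18 (-1.88 to 0.17). The same held for HSP101, HSFA2, APX1, NCED3, CAT2 and P5CS1, while RBCS1A and GPT2 stayed positive. Signal over background was not used here, so what it limits is unknown.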

Other observations

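Of the tests in this part, the count of splits for heat and drought at ambient CO2 per sample and the splits that keep the stress labels were chosen only after the result was seen, and the fits within arrays and between arrays were added after the samples were seen.

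Other splits of the same samples were counted. Per sample as labelled the real count was 0, so that every split gives as many by construction (35 of 35 in each of the 5 comparisons of 2 groups, and 100 of 100 drawn splits for the interaction), and this count says nothing about chance. The highest counts of the other splits were 2788 for stress at ambient CO2, 0 for stress at elevated CO2, 4457 for CO2 without stress, 7173 for CO2 under stress, 4359 for the combined treatment and 3107 for the interaction. Splits that call as many as 7173 probes where the labels call 0 point to a structure of the samples.

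Within arrays, the share of splits with as many probes was under 0.05 in all 6 comparisons, with no adjustment over the 6. This does not exclude chance. For 2 groups the real split alone makes up the smallest share possible. Other splits can put 2 samples of 1 group on an array, and in the stress comparisons they leave part of the stress difference in the residual spread. In the 5 comparisons of 2 groups only 1 split, the real one, gave as many. The real and the highest other counts were 10477 and 4 for stress at ambient CO2, 6850 and 0 for stress at elevated CO2, 33 and 12 for CO2 without stress, and 369 and 119 for CO2 under stress, each over 34 splits, and 7888 and 0 for the combined treatment over 33. For the interaction 3 of 91 splits gave as many as the real 876 and the highest other gave 10297, which again points to a structure of the samples. Those splits redraw all 16 labels, stress included. With the stress label of every sample kept and the CO2 labels redrawn, 1 of 90 splits, the real one, gave as many as 876, and the highest other gave 685. These counts do not bear on the direction of a difference. The real counts also rest on single arrays, since 33 fell to 0 without array 1.1, 369 to 5 without array 2.2 and 876 to 9 without array 1.2.

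Further lists were not called as a whole between stressed and unstressed arrays (cameraPR adjusted p above 0.05), while members did change past limma's threshold. Antioxidant genes rose in 11 and fell in 10 of 36 members, with the ascorbate synthesis gene VTC2 up (2.36) and the thylakoid peroxidase gene TAPX down (-1.29). Photorespiration had GGT1 (1.21) and GLU1 (1.18) up and DIT2 (-0.86) down, and the Calvin-Benson cycle had FBA1 up (1.23), with 3 rises and 3 falls of 17. Starch and sucrose genes rose in 9 and fell in 10 of 33, with BAM1 up (1.63) and SPS4F down (-1.42). Sugar starvation markers fell in 6 and rose in 2 of 12, including SEN5 (-1.38) and DIN10 (-1.22). Nitrogen genes included NRT1.1 (-1.86) and NIA2 (1.26), and phenylpropanoid genes PAL2 (-1.04) and FLS1 (-0.95). Desaturase genes FAD8 (-1.69) and FAD3 (-1.44) fell and FAD2 (1.04) rose. The clock genes RVE2 (1.98) and LNK1 (1.48) rose, at a harvest of one time of day. Jasmonate genes included CORI3 (1.35) and AOC1 (-1.15), and glucosinolate genes rose in 5 of 12, with BCAT4 at 0.98. Of the senescence genes SAG29 (1.85) and ORE1 (1.26) rose and SAG21 (-1.14) fell, and of 6 oxidative stress markers UPOX (0.99) and ELIP1 (0.97) rose.

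Lists with fewer than 5 measured members were described and not tested. Of 4 floral transition genes 3 rose, including FUL (0.95) and SVP (0.67). Of 4 floral organ genes PI (-0.78) and AP1 (-0.59) fell, of 4 guard cell genes TGG1 fell (-1.73), and the 1 measured root gene did not change past the threshold.

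Between arrays of elevated-CO2 and ambient samples, shifts also called by cameraPR were seen for clock genes (median -0.10, adjusted p = 0.0012, and 0.0076 with an estimated correlation), antioxidant genes (adjusted p = 0.035, and 0.025 with an estimated correlation) and nitrogen genes (adjusted p = 0.015, and 0.038 with an estimated correlation). Within arrays as labelled, the mean CO2 ratios ran against the between-array CO2 difference, with r over probes of -0.58 (-0.35, -0.15, -0.39 and -0.45 on the 4 arrays that pair the CO2 levels).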
